A study of Mus musculus with 2 samples.

How the data were processed

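Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of B6NCrl mouse embryos at 13.5 days, with both sexes mixed, per the labels. The labels number the 2 libraries as biological replicates 1 and 2, each made of 2 technical replicates. They form 1 group, so no comparison between conditions could be made, and the comparisons are between the replicates, between peaks and genome features, and between gene lists.

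The deposited files were 4 peak lists in narrowPeak form on the mouse build mm10. Per the text files deposited with the samples, 1 list came from the alignments of each replicate and 1 further file, 1 came from the alignments of both replicates together (the pooled peaks), and 1, the replicated peaks, was derived from the pooled and the replicates' lists. The aligner, the peak caller and the rule for a replicated peak were not given in the sources used here. For each peak the authors deposited a fold enrichment, which is a linear ratio over local or control background, a −log10 p-value, a −log10 q-value and the distance of the summit from the start. The fold is the authors' own value and served only to describe and rank peaks within 1 list. Read counts were not analysed here, so the sequencing depth of each replicate is unknown, and a place without a peak in a list is one where no enrichment was detected at that depth. The authors' lists hold peaks down to low stringency: 74.6% of the peaks of replicate 1, 75.4% of replicate 2, 90.4% of the pooled list and 99.6% of the replicated list had q at or below 0.05.

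The content of the replicated list was checked against the others. All 34843 replicated peaks stand in the pooled list under the same name and position. The list held all 24657 pooled peaks that overlapped peaks of both replicates over at least 50% of either peak, but 10050 of its peaks (28.8%) did not overlap a peak of both replicates by even 1 bp. Of these, 9596 overlapped a peak of 1 replicate and 454 of neither. The 24793 replicated peaks that overlapped a peak of both replicates were therefore used as an alternative, chosen after the data were seen.

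The sequence was GRCm38.p6 (the build mm10) with repeats in lower case, and the genes were those of GENCODE M21 on the same build. Peaks on the 19 autosomes, X and Y were analysed, and the 238 replicated peaks on scaffolds were left out of the tests. Coordinates are 1-based on mm10. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

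Overlap meant at least 1 bp. Chance overlap came from 1000 circular rotations of positions within each chromosome, in coordinates without N (200 rotations for the sequence content). The two-sided permutation p is double the smaller tail, so 0.002 is the smallest that 1000 rotations can give and 0.00995 the smallest that 200 can give. Peaks were assigned by their midpoint to a promoter (within 1 kb of a transcription start), an exon, an intron or intergenic sequence, in that order. For each of 23 gene lists, the share of protein-coding genes whose body overlapped a replicated peak was compared with 10000 random lists of the same size, drawn from other protein-coding genes matched in 20 bins of gene length (two-sided permutation test; 0.0002 is the smallest p they can give), with Benjamini-Hochberg adjustment over the 23 lists. Genes named for imprinting were also tested by promoter, within 2 kb of a transcription start, by Fisher's exact test. Zinc finger genes with peak bases were counted by the side of the gene midpoint that held more of them, with an exact sign test. Exact genome matches of 5 retroviral primer binding sites on both strands were counted within 1 kb of a replicated peak, with adjustment over the 5 sites. Peaks within 10 kb of each other were merged into domains. Intervals on shares are exact or Wilson 95% binomial intervals, as named, and cover counting error only. All tests treat genes, peaks or sites as the units within these 2 samples.

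The lists, motifs, and the tests and alternatives of the main comparisons were fixed before the data were examined, as was the rule for named genes: the 10 protein-coding genes with the highest-fold replicated peak that both replicates' peaks overlapped (1 gene per peak), the 10 with the most peak bases, up to 3 members of each list by fold (up to 6 for limb patterning, imprinted, germline and pluripotency genes), the genes of the 10 largest domains, and the first 3 members of a list without a peak, in the order of the list. Alternatives were each replicate alone, the pooled peaks, the upper 50% of peaks by the authors' −log10 p, other windows and overlaps, another chance model, and, added after the data were seen, the peaks in both replicates and the peaks whose summit 32-mer occurs once in the genome.

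The steps were tested on simulated data. Over 21911 real gene lengths, the list test called 3% of 200 unchanged lists of 40 genes, and 98.5% of 200 lists given 3 times the rate of peaks. These lists were drawn at random, with peaks independent between genes, so the rates need not hold for clustered genes that share peaks. The rotation test, on 50 pairs of lists of 1000 peaks on 1 chromosome, called 8% of independent pairs and 100% of pairs sharing 40% of their peaks, for which it measured a mean share of 40.6%. The simulated peaks were placed at random, so its rates need not hold for clustered peaks. The count of 32-mer copies was right for 100% of 100 planted sequences.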

Results

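H3K9me3 was profiled by ChIP-seq in E13.5 mouse limb in 2 biological replicates. Replicate 1 held 71395 peaks covering 21.3 Mb and replicate 2 held 62274 peaks covering 18.9 Mb, with median widths of 237 and 240 bp. The pooled list held 111487 peaks, and the replicated list 34843 peaks with a median width of 467 bp, covering 19.9 Mb with scaffolds included. Those on the chromosomes covered 0.741% of their sequence without N. The fold enrichment that the authors gave each replicated peak had a median of 3.62 and reached 16.96. Sequencing depth is unknown from these files, so a gene without a replicated peak is one at which none was detected, and it can still overlap a peak of either replicate.

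The strongest enrichment over protein-coding genes lay at Klf14, an intronless transcription factor gene of an imprinted region, where a 16.96-fold peak (chromosome 6, 30955618 to 30958885) with its summit in the coding exon covered 93.7% of the gene. The overlapping peaks of replicates 1 and 2 had folds of 16.7 and 14.0. A 12.5-fold peak overlapped the 5′ end of Tcfl5, a gene for a testis transcription factor, with its summit in intergenic sequence (chromosome 2, 180642665 to 180644671). Only 44 bp of the gene lay in it, and no peak of replicate 2 reached the gene. The protocadherin γ cluster held an 11.5-fold peak with its summit in a coding exon (chromosome 18, 37750799 to 37754830). Asmt, the last enzyme of melatonin synthesis, had an 11.2-fold peak on X (170674217 to 170678090) and 95.5% of its length in peaks. Of the other 6 genes of highest fold, 3 belonged to the fixed list of zinc finger genes: Zfp865 (10.9-fold), Zfp27 (10.6-fold) and Zfp810 (10.4-fold), each with the summit in a coding exon. The rest were Habp4 (10.5-fold, intron), 2610008E11Rik (9.98-fold, untranslated exon) and Sema6b (9.88-fold, summit intergenic).

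The first comparison asked how far the replicates placed peaks at the same sites. Of the peaks of replicate 1 on the chromosomes, 26401 of 71060 (37.2%) overlapped a peak of replicate 2, against 1.59% ± 0.161 (mean ± SD) after rotation. Of the peaks of replicate 2, 26432 of 61932 (42.7%) overlapped replicate 1, against 1.82% ± 0.182 after rotation. Both shares had a permutation p of 0.002, the smallest that 1000 rotations can give. The share was larger among peaks of higher fold. It was 25.6% in the decile of the peaks of replicate 1 with the lowest fold and 75.1% in the decile with the highest, and 32.2% and 77.96% in replicate 2.

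**Figure D1:**
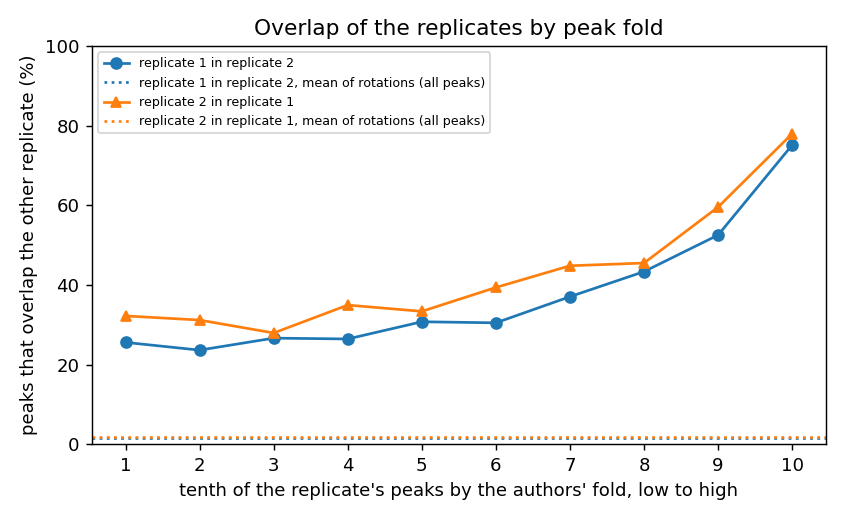
Percent of each replicate's peaks that overlapped the other replicate by at least 1 bp (y axis), by decile of the replicate's own peaks ordered by the authors' fold (x axis); dotted lines mark the mean of 1000 rotations over all peaks. The share reached 75.1% and 77.96% in the highest decile, against rotation means of 1.59% and 1.82%.

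Peaks were dense on chromosome 7 and sparse on X. The autosomes held 14.3 replicated peaks per Mb together, from 8.58 on chromosome 14 to 31.4 on chromosome 7, which had 2.38 times the density of the other autosomes. Chromosome 17 followed with 24.5 per Mb. Chromosome X held 378 replicated peaks, or 2.31 per Mb, which is 0.162 of the autosomal density. The replicates taken alone gave ratios of 0.240 and 0.337 and the pooled list 0.313, so the low density was present in each while its size varied. On X, 16.2% of the pooled peaks were in the replicated list, against 25.8% to 37.6% on the autosomes. The ratio of 0.162 thus depends in part on the choice of the replicated list. Y, of which 96.3% is repeat-masked, held 12 replicated peaks. Replicate 2 had more peaks on X (1391) than replicate 1 (1145), although it had fewer on each autosome.

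**Figure D2:**
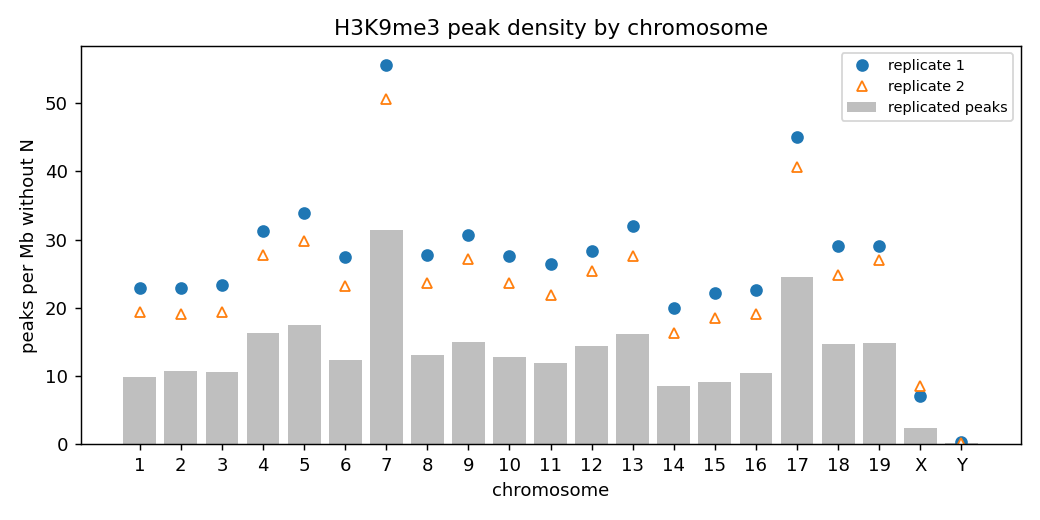
Peaks per Mb of sequence without N (y axis) on each chromosome (x axis); bars show the replicated peaks, circles replicate 1 and triangles replicate 2. Chromosome 7 had the highest density, 31.4 replicated peaks per Mb, and X had 2.31.

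Peaks favoured intergenic sequence over introns. Intergenic sequence held 56.2% of the replicated peaks against 49.9% ± 1.11 (mean ± SD of rotations), and introns held 34.4% against 42.2% ± 1.07. Exons held 3.88% against 3.20% ± 0.161, and promoters 5.46% against 4.71% ± 0.222. All 4 differences had a permutation p of 0.002, the smallest possible. With the pooled peaks, the excess was not past the threshold at exons (3.18%, permutation p = 0.709) or promoters (4.90%, permutation p = 0.0699).

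Zinc finger, vomeronasal receptor, clustered protocadherin, germline and imprinted genes carried replicated peaks more often than genes of matched length. Of 21911 protein-coding genes, 4610 (21.04%) overlapped a replicated peak. Among 23 lists, 7 were above and 1 was below the matched genes. Zinc finger genes, many of which encode transcriptional repressors, had a peak in 193 of 421 cases (45.8%, against 16.6% in matched lists). Vomeronasal receptor genes, for pheromone receptors, had one in 99 of 326 (30.4% against 11.4%), led by Vmn2r10 (6.26-fold), Vmn2r60 (5.93-fold) and Vmn1r81 (5.76-fold). Clustered protocadherin genes, for neuronal adhesion proteins, had one in 52 of 56 (92.9% against 36.8%). The annotated bodies of γ genes such as Pcdhga1 and Pcdhgc3 end at the same base, so nested genes share peaks. Within 2 kb of their own transcription starts, 51 of the 56 had a peak, against 3.79% of matched genes. These 3 lists had an adjusted p of 0.000767, from the smallest p that 10000 lists can give, and rotation of the genes, which keeps clusters together, left adjusted p values of 0.0153 to 0.0184.

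Germline genes, which act in germ cells and meiosis, had a peak in 24 of 43 cases (55.8% against 23.7%, adjusted permutation p = 0.000767). In 18 of the 43 the peak lay within 2 kb of a transcription start, against 4.196% of matched genes. Examples were Dazl, an RNA-binding regulator of germ cells, with a 7.24-fold peak across its start (chromosome 17, 50293004 to 50294466), Ddx4, the germ cell RNA helicase Vasa (6.09-fold; chromosome 13, 112651623 to 112652824), and Dmc1, a meiotic recombinase (5.10-fold; chromosome 15, 79604994 to 79605297). Tdrd1 (4.78-fold), Meioc (4.61-fold) and Piwil1 (4.28-fold) followed, and of the peak at Tdrd1 only the counterpart in replicate 2 was called. Sycp3, Syce1 and Syce2 had no replicated peak, although Sycp3 held 214 bp of a peak of replicate 1.

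Olfactory receptor genes (94 of 1092, 8.61% against 5.97%, adjusted permutation p = 0.000767) and cytochrome P450 family 2 genes (17 of 48, 35.4% against 17.5%, adjusted permutation p = 0.00986) were also above the matched lists. The leading members were Olfr139 (5.10-fold) and Cyp2c38 (5.60-fold). Neither call held under rotation of the genes, where the expected shares were 8.24% and 22.9% (adjusted permutation p = 0.943 and 0.521). Over all settings, adjusted permutation p ran from 0.000767 to 0.943 for olfactory receptor genes and from 0.00131 to 0.521 for cytochrome P450 family 2 genes, and both calls also ended with the upper 50% of peaks by −log10 p (adjusted permutation p = 0.689 and 0.149).

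Limb patterning genes carried fewer peaks than matched genes, 3 of 43 (6.98% against 22.0%, adjusted permutation p = 0.0213). The members with a peak were Bmp7, a bone morphogenetic protein (4.28-fold, untranslated exon), Gli3, an effector of hedgehog signalling (3.71-fold, untranslated exon), and Tbx4, a hindlimb regulator (3.06-fold, intron). Shh, Fgf4 and Fgf8 had no replicated peak. The share stayed below that of matched genes but not past the threshold with replicate 1 alone (23.3% against 34.4%, adjusted permutation p = 0.231), replicate 2 alone (20.9% against 30.7%, 0.353) and the pooled peaks (34.9% against 40.9%, 0.557). The call also ended with the upper 50% of peaks, the peaks in both replicates, bodies extended by 5 kb, transcription starts and at least 500 bp of peak bases, and adjusted permutation p ran from 0.0195 to 0.557 over all settings.

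The other 15 lists did not pass the threshold (adjusted permutation p from 0.202 to 1). None of 39 Hox genes, 68 histone genes or 22 major urinary protein genes had a replicated peak, against 7.66%, 3.52% and 6.08% of matched genes. Peaks were found at 1 of 34 Rhox genes, 1 of 103 keratin genes, 1 of 76 ribosomal protein genes, 2 of 28 housekeeping genes and 5 of 64 defensin genes. Cartilage and bone genes had peaks in 7 of 29 cases (24.1% against 23.4%), with intronic peaks at Sox5 (5.48-fold), Sox6 (5.27-fold) and Runx2 (5.10-fold) and none at Sox9. Skeletal muscle genes had 4 of 24, with Ckm at 4.19-fold. Markers of other cell types of the limb had 3 of 23, liver genes 2 of 20, neuronal genes 7 of 20 and pluripotency genes 2 of 18, Esrrb (4.78-fold) and Zfp42 (4.12-fold). Among genes of H3K9 methylation itself, 8 of 26 had a peak, led by Atf7ip (5.93-fold), a cofactor of the methyltransferase SETDB1.

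**Figure D3:**
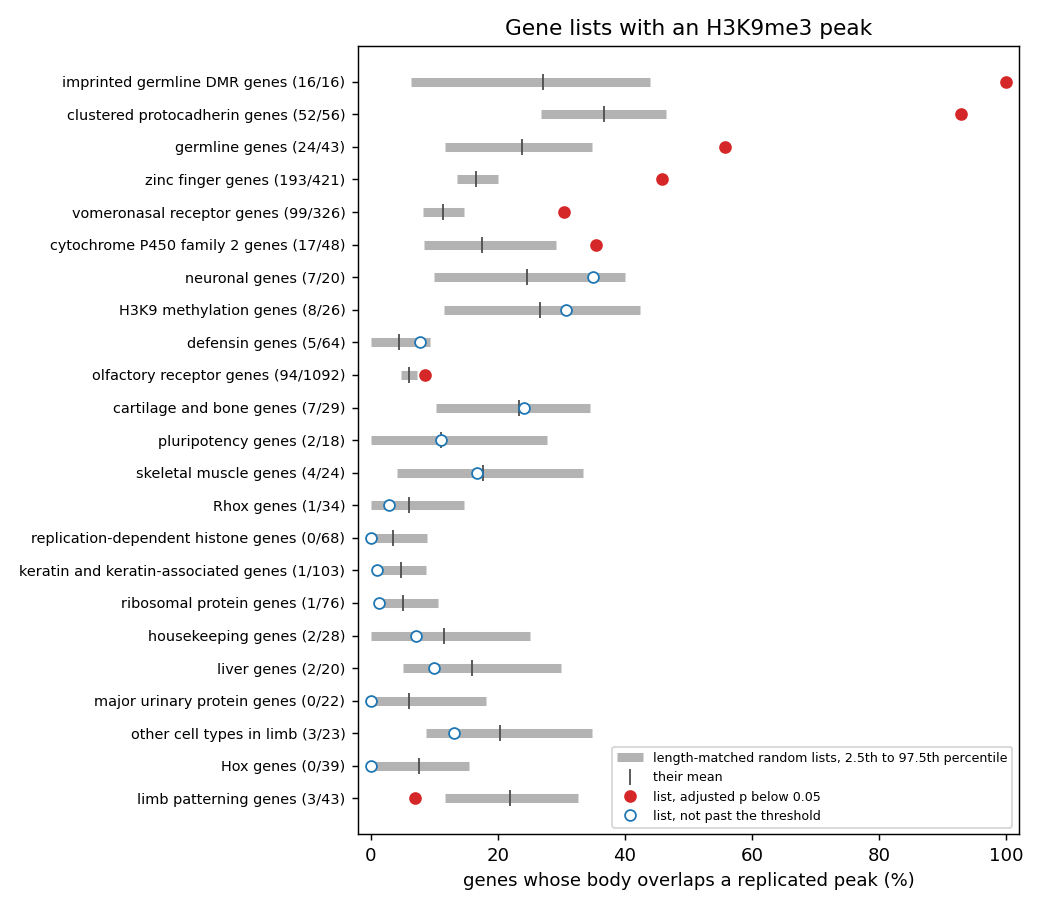
Percent of the genes of each list whose body overlapped a replicated peak (x axis; counts beside the names), where grey bars span the central 95% of 10000 length-matched random lists and ticks their mean; filled red circles passed an adjusted p of 0.05 and open blue circles did not. Imprinted genes (100%) and clustered protocadherins (92.9%) lay farthest above their matched lists, and limb patterning genes (6.98%) lay below.

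Promoters of genes with a germline differentially methylated region, the elements that control imprinting, carried peaks almost throughout. All 16 protein-coding members of this list overlapped a replicated peak over the gene body (27.1% in matched lists, adjusted permutation p = 0.000767). A replicated peak lay within 2 kb of a transcription start in 20 of 22 such genes, noncoding genes included (90.9%, exact 95% interval 70.8 to 98.9), against 969 of 21895 other protein-coding genes (4.43%; Fisher's exact test, two-sided, p = 2.16e-25). Both replicates had a peak at all 20. The 20 genes shared 18 distinct peaks, because neighbours such as Peg10 and Sgce, or Gnas and Nespas, lie at the same element, so the genes are not fully independent. Folds ran from 3.62 at Mcts2 to 7.74 at Plagl1, a growth-regulating zinc finger gene (intron; chromosome 10, 13089842 to 13092735). Nnat (7.57-fold; chromosome 2, 157556685 to 157560750), Grb10, a growth inhibitor (7.41-fold; chromosome 11, 12025230 to 12027556), Mest (7.24-fold; chromosome 6, 30736333 to 30738988) and the 7038 bp peak at Gnas and Nespas (7.24-fold; chromosome 2, 174294248 to 174301285) followed. The H19 peak (5.10-fold; chromosome 7, 142579901 to 142582854) was intergenic, outside the gene body. Rasgrf1 and Zdbf2 had no peak within the window, and the nearest replicated peaks, inside the gene bodies, lay 16.0 kb and 5.33 kb from a transcription start. The positions of the differentially methylated regions themselves were not used. A peak within the window, or the lack of one, therefore does not show whether the region itself carries the mark.

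In zinc finger genes the peaks lay toward the 3′ end, where the exons for the finger arrays lie. Of 193 such genes with peak bases, 151 had more of them on the 3′ side of the gene midpoint and 42 on the 5′ side (78.2%, exact sign test, two-sided, p = 1.24e-15). In other protein-coding genes no such preference was detected by this count (2180 against 2236, 49.4%, p = 0.408), and the groups differed (Fisher's exact test, p = 7.60e-16). Coverage of zinc finger genes by replicated peaks rose from 0.975% of bases in the first decile of the gene to 8.29% in the last. It was 0.840% and 0.726% in other genes. When the last and first exons were compared, the last was more covered in 122 zinc finger genes and the first in 8 (93.8%, exact sign test, p = 2.55e-27). Other genes leaned the same way, 391 to 174 (69.2%, exact sign test, p = 3.49e-20), but less strongly (Fisher's exact test, p = 2.41e-10). Exon lengths were not matched, and a longer exon meets a peak more often, so either lean may come in part from length.

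**Figure D4:**
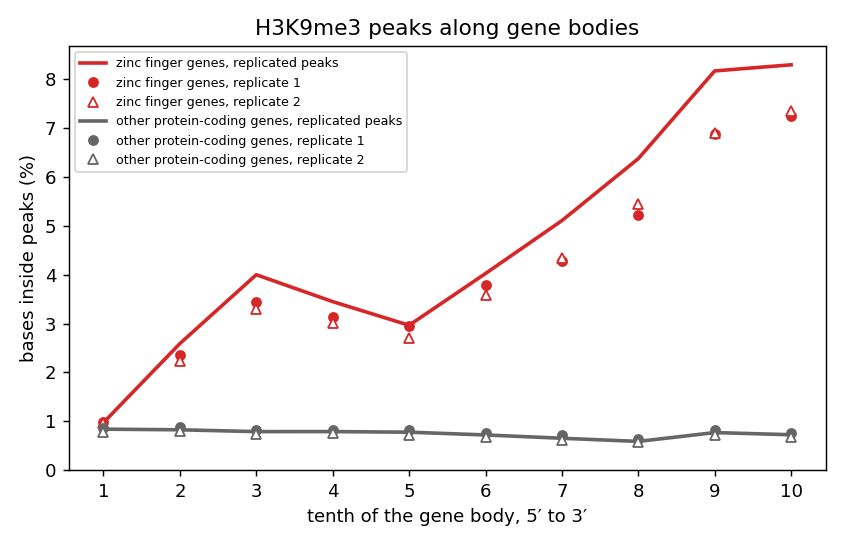
Percent of bases inside peaks (y axis) by decile of the gene body from 5′ to 3′ (x axis), for zinc finger genes (red) and other protein-coding genes (grey); lines show the replicated peaks, circles replicate 1 and triangles replicate 2. Coverage of zinc finger genes reached 8.29% in the last decile, against 0.726% in other genes.

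Repeat-masked sequence made up 33.8% of the bases of replicated peaks, against 33.7% ± 0.555 (mean ± SD of 200 rotations; permutation p = 0.826), so no difference was detected. The rotations also fell on sequence where reads cannot be placed uniquely. On the autosomes, 94.5% of the summits lay on a 32-mer found once in the genome, against 84.8% of random positions. An excess of peaks in repeats could therefore have been missed. Within 200 bp around the summits the share was 35.5% against 33.8% ± 0.518, with the smallest p that 200 rotations can give (0.00995). The GC content of the peaks was 46.2% against 42.1% ± 0.217, with the same p. Peaks lay close to the primer binding sites of endogenous retroviruses, at which a transfer RNA primes reverse transcription. All 5 sites had an adjusted permutation p of 0.002, the smallest possible. The tRNA-Lys1,2 site of MusD and ETn elements (TGGCGCCCAACGTGGGGC) lay within 1 kb of a replicated peak in 32 of 67 exact matches (47.8%, Wilson 95% interval 36.2 to 59.5, against 3.25% after rotation). The tRNA-Pro site of murine leukaemia virus-like elements (TGGGGGCTCGTCCGGGAT) did so in 58 of 174 (33.3%, 26.8 to 40.6, against 2.34%), and the tRNA-Lys3 site (TGGCGCCCGAACAGGGAC) in 19 of 62 (30.6%, 20.6 to 43.0, against 2.84%). The tRNA-Phe site of intracisternal A particles (TGGTGCCGAAACCCGGGA), the most numerous, did so in 179 of 1090 (16.4%, 14.3 to 18.7, against 2.90%). The tRNA-Gln site (TGGAGGTCCCACCGAGAT) did so in 12 of 93 (12.9%, 7.54 to 21.2, against 2.91%), and its call ended at a distance of 5 kb (adjusted permutation p = 0.120). When the match itself had to lie inside a peak, 8 of the 1090 tRNA-Phe sites did (0.734% against 0.719%, adjusted permutation p = 1), while 9 of the 67 tRNA-Lys1,2 sites did (13.4% against 0.788%). Peaks were seldom called on sequence present in many copies. On the autosomes, 1.28% of summits lay on a 32-mer with 10 or more copies, against 10.3% of random positions. A site without a peak on it is therefore not shown to lack the mark, and the sites cannot be ranked by these counts.

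**Figure D5:**
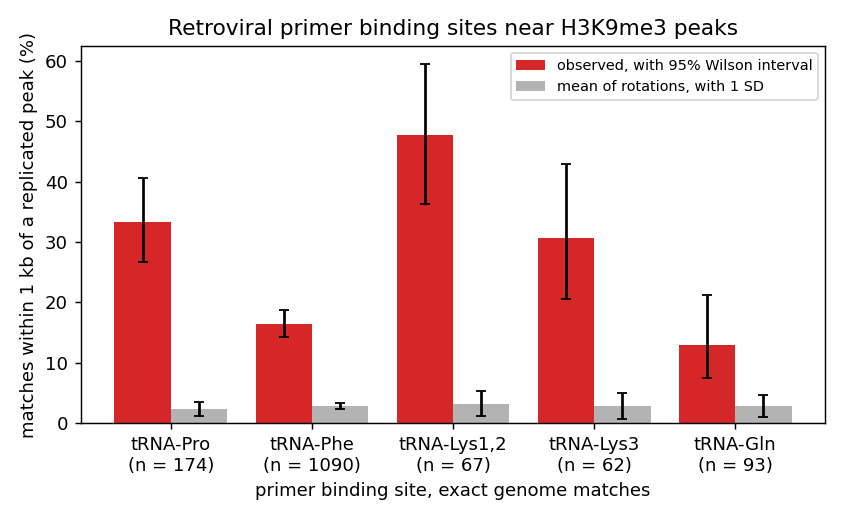
Percent of exact genome matches of each primer binding site within 1 kb of a replicated peak (y axis), by site (x axis). Red bars show the observed share with its 95% Wilson interval and grey bars the mean of 1000 rotations with 1 SD; the observed shares ran from 12.9% to 47.8% and the rotation means from 2.34% to 3.25%.

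Domains were described without a test against chance. Merging replicated peaks within 10 kb gave 19482 domains, of which 5178 held at least 2 peaks and together 58.7% of all peaks. Replicates 1 and 2 alone gave 36377 and 31679 domains, 12409 and 10447 with at least 2 peaks, 557 and 511 with at least 10, and longest spans of 199.7 and 137.5 kb in place of 303.2 kb. Of the 314 domains with at least 10 peaks, 39 overlapped a zinc finger gene. The 10 largest by peak length lay on chromosomes 7 (6 domains), 18 (2), 1 and 4. The first spanned 303.2 kb with 142 peaks (chromosome 7, 17884579 to 18187735) over Ceacam11, Ceacam12, Ceacam13 and Igfl3. The second covered the part of the protocadherin γ cluster from Pcdhga1 to Pcdhga12 (chromosome 18, 37593922 to 37777074) with 106.2 kb of peaks in 183.2 kb, and another lay over Pcdhb9 to Pcdhb22. In Pcdhga1, 51.8% of the gene lay in peaks, while the C-type genes Pcdhgc3 and Pcdhgc4, at the end of the same cluster, had no replicated peak, although both held 203 bp of a peak of replicate 1. Further domains lay over secretoglobin genes such as Scgb2b24 and Scgb1b24, vomeronasal genes such as Vmn1r74 to Vmn1r76, and Nlrp4e and Nlrp5. The most continuous of the 10 covered the Ugt1a genes for glucuronidation enzymes with Mroh2a and Hjurp (chromosome 1, 88203554 to 88266734), where peaks filled 79.7% of 63.2 kb.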

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

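The test of lower depth on X and the comparison of zinc finger genes with other genes were chosen after the results they bear on had been seen.

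Scaffolds outside the chromosomes, which were left out of the tests above, held 238 replicated peaks. They lay on 24 scaffolds, and 66 of them on 1 scaffold, chrUn_JH584304. Their median fold was 4.01 against 3.62 on the chromosomes, and 93.7% of them overlapped a peak of both replicates. Their median −log10 p was 18.8 against 7.63, a far larger gap than that in fold. Its cause was not tested, so the overlap between replicates does not show that the mark is enriched on these scaffolds.

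The low density of peaks on X was present in each list. Lower depth may add to it, since X is present in fewer copies than the autosomes where sexes are pooled, but as the whole cause it is argued against by the pooled list, in which the autosomes had 3.19 times the density of X, while the step from the pooled list to a single replicate, at an unknown share of the reads, lowered autosomal density only 1.67 times. Fewer mappable positions are argued against as the whole cause by the replicated peaks per Mb of sequence with unique 32-mers. There were 3.32 on X against 10.7 to 39.7 on the autosomes. By this measure Y had 3.35, close to X, although from 12 replicated peaks. The genes of the 7 higher lists, some of which lie on X, are argued against as the whole cause by the sequence outside 100 kb of them. It held 12.4 replicated peaks per Mb on the autosomes and 2.20 on X. The autosomal density there was still 5.36 times that of X as a whole. Within that distance lay 18.3% of autosomal peaks. The counts by unique 32-mers and outside these genes used only the replicated peaks, in which X was lower than in the pooled list. Clusters that belong to none of the lists, such as the Ceacam and secretoglobin genes, were not removed as such. The absence from X of peak-rich clusters in general was therefore not tested. A combination of these, and a biological cause tied to the pooled sexes or to X itself, stay open, as untested.

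The 3′ position of peaks in zinc finger genes could come from reads shared between similar finger arrays. With only the peaks whose summit 32-mer occurs once in the genome, 145 genes had more peak bases on the 3′ side and 45 on the 5′ side (76.3%, exact sign test, p = 1.84e-13), which argues against it as the whole cause, although the length of the reads is not given here. A 3′ preference of all genes is argued against as the whole cause by the 49.4% in other protein-coding genes. Between the last and the first exon other genes also leaned to the 3′ end (69.2% against 93.8% in zinc finger genes, Fisher's exact test, p = 2.41e-10). That count was not matched for exon length, and a longer exon meets a peak more often, so whether a shared preference contributes stays open. The design gives no second group, so no biological explanation was tested.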

How the results depend on the processing

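The peaks in both replicates and those with a unique summit 32-mer were chosen as alternatives after the data were seen, and the other alternatives below before the data were examined. Of 128 comparisons of a main result with an alternative, 105 kept their direction and side of the threshold or, for counts, stayed within 1.5 times the main count or, for chromosome densities, within 1 SD between the replicates, and none reversed. Of 230 comparisons of single gene lists, 207 kept their call, 16 were no longer past the threshold and 7 newly passed it. Without replicate 1 or 2, the density of X over the autosomes (0.162) was 0.240 to 0.337, that of chromosome 7 over the other autosomes (2.38) was 2.02 to 2.14, the number of lower gene lists (1) was 1 to 2 and that of domains with at least 10 peaks (314) was 511 to 557. With the pooled peaks these were 0.313, 1.94, 2 and 875, and the shares of peaks at exons and promoters were 3.18% (permutation p = 0.709) and 4.90% (permutation p = 0.0699), no longer past the threshold. With the upper 50% of peaks by −log10 p there were 0 lower lists and 143 such domains. With the peaks in both replicates, chromosome 7 had 2.47 times the density and 0 lists were lower. Lower lists numbered 2 with gene bodies extended by 5 kb, 0 within 2 kb of transcription starts and 0 with at least 500 bp of peak bases. Limb patterning genes were not among the lower lists in any of these settings, which were histone and ribosomal protein genes with replicate 1 alone, keratin genes with replicate 2 alone, keratin and ribosomal protein genes with the pooled peaks, and Hox and histone genes at 5 kb. Higher lists (7) numbered 6 with the pooled peaks and within 2 kb of transcription starts, without cytochrome P450 family 2 genes, and 5 with the upper 50% of peaks, 500 bp and rotation of the genes, also without olfactory receptor genes. The repeat-masked share passed the threshold only within 200 bp around the summit (35.5%). The tRNA-Gln site at 5 kb (15.1%) and the tRNA-Phe site inside the peak (0.734%) were no longer past it. The cause was not tested. Sequencing depth is unknown, so it cannot be said which absent peaks lie below the limit of detection.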

Other observations

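The family scan and its rotation test, and the comparison of hexamers, were chosen after the main results had been seen, with each bound set before its own result was known. Leaving out each imprinted peak in turn was added after the hexamer result had been seen, and so was the comparison of expected shares under rotation after the family calls.

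Families outside the fixed lists also carried peaks. Among 232 families of at least 10 protein-coding genes that share a symbol stem, 4 had more genes with a replicated peak than matched lists (adjusted permutation p below the threshold over the 232) and none had fewer. Secretoglobin genes, for small secreted proteins, had a peak in 11 of 34 cases (32.4% against 3.54%, adjusted permutation p = 0.0232). Pregnancy-specific glycoprotein genes (Psg) had one in 8 of 13 (61.5% against 10.96%, adjusted permutation p = 0.0232), Ceacam genes in 8 of 15 (53.3% against 10.9%, adjusted permutation p = 0.0348) and Klra genes, for natural killer cell receptors, in 7 of 11 (63.6% against 15.2%, adjusted permutation p = 0.0348). The Psg, Ceacam and Klra genes each lie on 1 chromosome. For Ceacam genes it is chromosome 7, which had the highest peak density, and secretoglobin genes such as Scgb2b24 lie there too. The matched lists were matched on gene length and not on chromosome. Whether the 4 families neighbour each other was not examined, so they need not be independent. A candidate explanation is that whole clusters lie in peak-rich regions. Under rotation of the genes, which keeps clusters together, 25% of the 4 calls held, that of the secretoglobin genes (6.54% expected, adjusted permutation p over the 4 of 0.0480). The other calls ended at adjusted permutation p of 0.0719 to 0.104, although the expected shares rose only to 19.05% for Psg, 17.6% for Klra and 18.8% for Ceacam genes. Rotation widened the range of chance, whose central 95% reached 69.2%, 54.5% and 53.3%, and the call of Klra genes ended only with adjustment (unadjusted permutation p = 0.0480), so the explanation stays open for these families.

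The peaks at imprinted promoters may mark elements bound by ZFP57, which recognises the methylated hexamer TGCCGC. The 18 imprinted peaks held 100 copies in 51.0 kb, or 1.96 per kb, against 0.189 per kb in 1442 other replicated peaks within 2 kb of a transcription start of a protein-coding gene. At 10.4 times, this was the highest ratio among 112 hexamers with the same number of CG and of G or C bases, a rank in the top 0.893%, and the median ratio of the 112 was 2.27. The next hexamer had a ratio of 8.79. The ratio stayed between 9.63 and 11.1 when any 1 imprinted peak was left out, and 15 of the 18 peaks held at least 1 copy. Imprinted peaks were richer in CG (40.5 against 16.9 per kb), which the comparison among hexamers takes into account only in part. The imprinted peaks were picked by a fixed list of imprinted genes, and both groups of peaks carry the mark. The excess can therefore come from the choice of loci alone and does not tie the mark to ZFP57. Binding itself was not measured.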
